A study of Mus musculus with 6 samples.

How the data were processed

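Total RNA of 6 cultures of mouse ES cells, 3 with Scc1 lox/lox ERT2-Cre and 3 with Scc1 wt/wt ERT2-Cre, was measured on Affymetrix Mouse Gene 1.0 ST arrays after 24 h with 4-OHT. Per the labels' protocols, cells were kept on laminin, RNA was taken with a column kit and biotin-labelled with the maker's terminal labelling kit. Per the design text, the 3 samples of each genotype were biological replicates. The dose of 4-OHT reads 80 nM in the sample labels but is in mM in the design text, and the dose of the labels is printed here. Each sample's genotype and replicate number were taken from its labels.

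The deposited table holds log2 values of 35556 probe sets on each array, which the authors made with RMA and the affy package per the submitters' processing notes. Versions, genome build and options are not given in the sources used here. The usual RMA steps are background correction, quantile normalization and a median polish of the probes of each probe set. Medians of the 6 columns differed slightly (4.94, 4.85 and 4.90 in wt/wt replicates 1 to 3, and 4.93, 4.93 and 4.87 in lox/lox replicates 1 to 3), so the columns do not share identical quantiles. RMA assumes that the total distribution is alike between arrays, so an overall rise or fall of RNA per cell cannot be seen. Background keeps weak genes above 0, so a fold change of a gene near the array median understates the change. No detection calls were used.

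Probe sets were named through the platform annotation. Exactly 1 gene symbol was given for 21789 probe sets, several for 1621, and 12146 are unnamed here. Of the single-gene probe sets, 21698 had an Entrez ID in the mouse gene table of assembly GRCm38.p6, and 0 symbols had to be updated. That table also gave each gene's chromosome and order, and no coordinates are printed. Each gene was represented by the probe set with the highest mean over the 6 arrays, which left 19938 genes, of which 999 had more than 1 probe set. Of the called genes, 72 had several probe sets, and 7 of these had one of opposite sign. No genes were filtered out as dim.

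Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, lox/lox minus wt/wt, 6.14 prior and 4 residual degrees of freedom), and genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. These p-values measure the spread between 3 replicates per genotype. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over 29 lists, beside camera with an estimated correlation and fry. No list passed with an estimated correlation, in which p53 targets and primed genes had unadjusted p of 0.00593 and 0.0312. The median, mean and camera direction differed in sign in 7 lists, 0 of them called. Counts adjusted over the list alone use the members of that list. The number of called members was set against 10000 random lists matched on mean expression, for imprinted genes and, after that result was seen, for all 29 lists. Chromosomes were tested like lists, and the 50 measured neighbours on each side of Rad21 by Fisher's exact test. The design, lists, alternatives and rule for named genes were fixed before the data were examined.

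The rule named Rad21, Myc, Pou5f1, Sox2 and Nanog in any case. It added the 12 higher and 12 lower genes with the largest log2 change among called genes whose arrays did not overlap between genotypes, leaving gene models named by a clone or number unnamed, and up to 4 members with the smallest p of each list described. Some further list members and the called neighbours of Rad21 were named outside the rule, after their values were seen. In most lists nearly all members had a probe set of their own. The list of 2-cell-like cells had 6 of 18, that of imprinted genes 22 of 29, and that of p53 targets 23 of 26. The other members were on probe sets with several symbols or on none named here, and were not analysed here.

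The fitting code was tested on simulated arrays with 200 of 19938 genes changed between lox/lox and wt/wt. Of genes with a true log2 change of 0.5, 55.2% were recovered, of those with 1, 94%, and of those with 2, 100%. Among the calls 1.8% were unchanged genes, and 0 genes were called when none was changed. When p53 targets alone were shifted by 0.3, 1 list was called, the right one. That shift exceeded the median of 0.15 measured for this list, and the noise of each simulated gene was drawn independently. The simulation therefore does not cover lists whose members correlate.

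Alternatives were quantile normalization, median centring and cyclic loess, a filter on dim genes (8519 genes at or below a mean of 4.90 removed), all probe sets, eBayes with trend and robust, array weights, the replicate number as a block, each array left out in turn, an adjusted p under 0.01, and a change of at least 1.5-fold. Leaving out both arrays that stood apart within their genotypes, or marking them with a covariate, was chosen after seeing the data. Samples without 4-OHT were not analysed here.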

Results

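Gene expression was measured on 6 Affymetrix Mouse Gene 1.0 ST arrays, 1 per sample, in mouse embryonic stem (ES) cells from a female, mixed strain background. The cells grew in serum-free N2B27 medium with LIF and 2i, a pair of kinase inhibitors that holds ES cells in the naive pluripotent state. Both genotypes carried ERT2-Cre, a Cre recombinase that enters the nucleus when 4-hydroxytamoxifen (4-OHT) is added. In 3 samples both alleles of Scc1 were flanked by lox sites (lox/lox), so that Cre can excise the gene, and in 3 control samples both alleles were wild type (wt/wt). Scc1 is the older name of Rad21, which encodes the subunit that closes the cohesin ring, the complex that holds sister chromatids together and shapes chromatin loops. All 6 samples had received 4-OHT for 24 h, at 80 nM per the sample labels, and no sample without 4-OHT entered the comparison. A difference between the genotypes therefore takes in the loss of Rad21 and anything in which the cell lines differed before treatment.

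The medians of the 35556 log2 values per array lay between 4.85 and 4.94. Correlations between pairs of arrays ran from 0.9892 to 0.9947, and those within a genotype from 0.9922 to 0.9947, so no array was a copy of another. Within the genotypes, the first component of the deviations from the group means carried 41.2% of their variance. On it wt/wt replicate 2 and lox/lox replicate 3 (loadings -0.576 and -0.537) stood apart from the other arrays, at 0.101 to 0.475. The highest loading was that of wt/wt replicate 1, so the wt/wt arrays spread to both ends. The precision is limited by the number of arrays, 3 per genotype.

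The first question was whether the targeted gene had been lost. Rad21 stood at 10.02 ± 0.03 in wt/wt and 6.09 ± 0.04 in lox/lox cells (log2 intensity, mean ± SD, n = 3), a 15.2-fold lower level. The log2 change was -3.93 with a standard error of 0.07, and its adjusted p of 1.57e-09 in limma was the smallest of all genes. Every lox/lox array lay between 6.06 and 6.14, and every wt/wt array between 9.99 and 10.05. Of the 18 measured cohesin subunits and regulators, 3 passed the test, and 4 did when adjusted over the list alone. Besides Rad21 these were Stag2, an X-linked core subunit, at a log2 change of 0.54 (SE 0.09, adjusted p = 0.00592), and Pttg1, the securin that inhibits separase, at -0.45 (SE 0.10, adjusted p = 0.0244). The call of Pttg1 was lost without wt/wt replicate 2 or 3 or lox/lox replicate 2 or 3, with an adjusted p of up to 0.116. Hdac8, which deacetylates Smc3, had a log2 change of -0.33 and did not pass (adjusted p = 0.0728). The list as a whole was not shifted against other genes (camera adjusted p = 0.605), with a median of 0.005 and a mean of -0.22 that rests on Rad21. Among 5 meiotic cohesin genes none passed in limma, where 2 had an unadjusted p under 0.05, and adjusted over the list alone 1 was higher and 1 lower (camera adjusted p = 0.663). Without wt/wt replicate 1 there was 1 lower member, and without lox/lox replicate 1 there was 1 higher. Rec8, the meiotic counterpart of Rad21, had a log2 change of -0.36 (adjusted p = 0.0968).

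**Figure D1:**
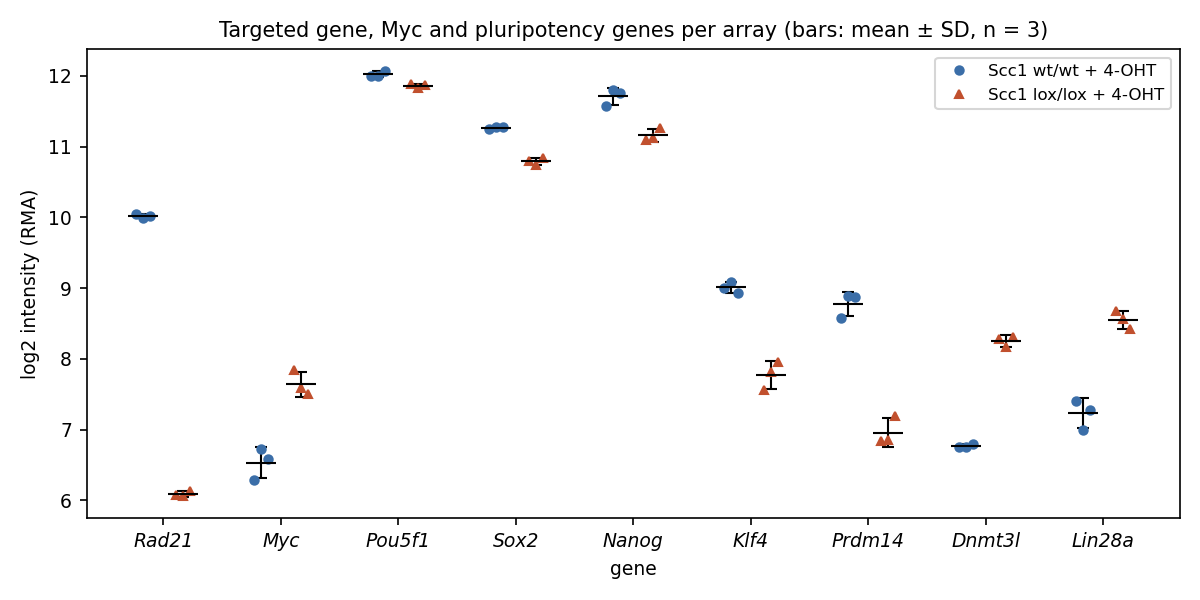
Log2 intensity (vertical axis, RMA scale) of 9 genes (horizontal axis) on each of the 6 arrays, with wt/wt arrays as blue circles, lox/lox arrays as red triangles and bars for the mean and SD of 3 arrays. Rad21 fell by 3.93 on the log2 scale, Myc rose by 1.11, and Pou5f1 differed by -0.16, which did not pass the adjusted threshold.

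Many genes besides Rad21 differed between the genotypes, most of them by small amounts. Of 19938 genes tested, 1228 (6.16%) differed between the genotypes at an adjusted p under 0.05 in limma, 508 higher and 720 lower in lox/lox cells. A change of at least 1.5-fold was seen in 184 of the higher and 267 of the lower genes, and one of at least 2-fold in 36 and 62. In all 1228 genes the 3 arrays of one genotype lay above the 3 of the other. Such separation was seen in 22.8% of all genes, where chance gives 10%. The count moved with single arrays. It was 806 without wt/wt replicate 2, 661 without wt/wt replicate 3 and 626 without lox/lox replicate 2. The higher genes numbered 269 without wt/wt replicate 3 and 286 without lox/lox replicate 2. The lower genes numbered 461 without wt/wt replicate 2, 392 without wt/wt replicate 3, 475 without lox/lox replicate 1 and 340 without lox/lox replicate 2. All 6 fits that each left out 1 array kept 543 genes, 233 higher and 310 lower. Without both arrays that stood apart, an alternative chosen after seeing the data, 697 genes were called, of which 267 were higher and 430 lower.

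Among the 12 largest increases, Nod1, a cytosolic sensor of bacterial peptidoglycan, was 6.36-fold higher in lox/lox cells (log2 change 2.67, SE 0.10, adjusted p = 4.09e-07). It rose from 4.91 ± 0.16, close to the array median, to 7.58 ± 0.08 (n = 3). Trh, which encodes the precursor of thyrotropin-releasing hormone, was 6.18-fold higher (adjusted p = 1.84e-05) and reached 12.21 ± 0.14 in lox/lox cells. Ubd, a ubiquitin-like modifier, was 4.41-fold higher, and Usp26, an X-linked ubiquitin protease, 3.52-fold. Lefty1, a secreted inhibitor of Nodal signalling, was 3.48-fold higher (log2 change 1.80, SE 0.22, adjusted p = 0.00112). The amino acid transporter subunit Slc7a7, the tight junction protein Cldn6 and the lipase Liph were 3.18-, 3.16- and 3.13-fold higher. The egg coat glycoprotein gene Zp3 was 3.05-fold higher, the neuronal filament gene Ina 3.04-fold, Dnmt3l, a cofactor of de novo DNA methylation, 2.80-fold, and the aldehyde oxidase gene Aox3 2.75-fold. One further gene model known by a number lay in this range.

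The 12 largest decreases began with Rad21. Plagl1, an imprinted zinc finger gene, was 5.47-fold lower in lox/lox cells (log2 change -2.45, SE 0.16, adjusted p = 3.10e-05) and fell from 8.43 ± 0.20 to 5.98 ± 0.34. Cd3g, known as a part of the T cell receptor complex, was 5.24-fold lower, Ak4, a mitochondrial adenylate kinase, 5.21-fold, and the autophagy receptor gene Calcoco2 4.20-fold. The second probe sets of Ak4 and Calcoco2 had log2 changes of -1.97 and -1.84. Elf3, an ETS transcription factor of epithelia, was 4.01-fold lower, the secreted protease gene Htra1 3.73-fold, and Sik1, a salt-inducible kinase, 3.62-fold (adjusted p = 9.84e-06). Abca1, which exports cholesterol, was 3.58-fold lower, Prdm14, a regulator of pluripotent and germ cells, 3.52-fold, Tet2, which oxidises 5-methylcytosine, 3.41-fold, and the homeobox gene Meis2 3.38-fold. Another 2 gene models known by a clone or number lay in this range. The adjusted p of each gene named among the 12 increases and 12 decreases was at most 0.00142.

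**Figure D2:**
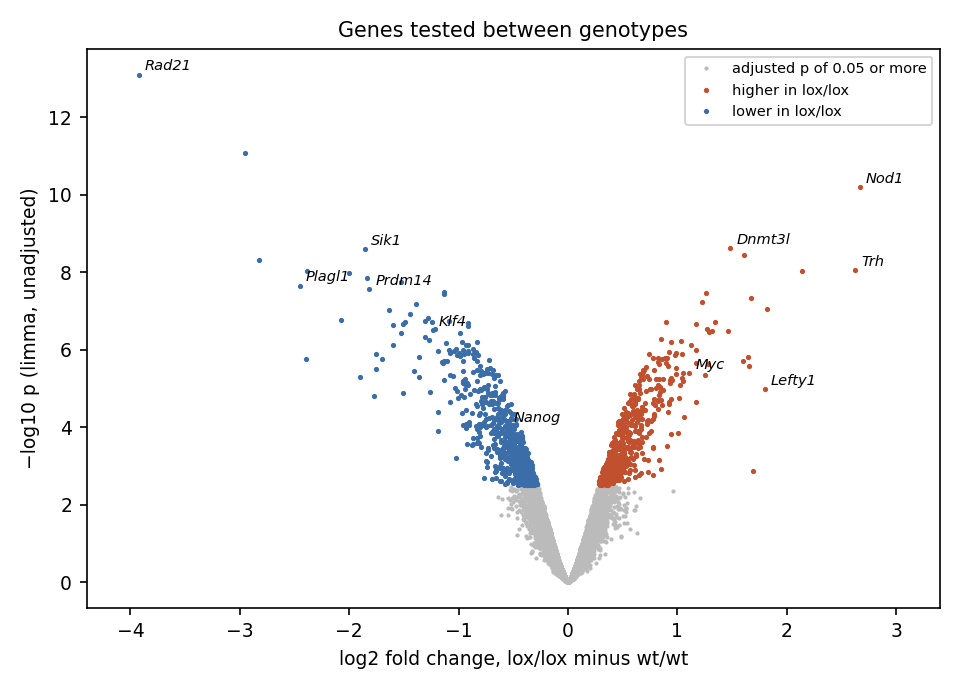
Log2 fold change between lox/lox and wt/wt cells (horizontal axis) against -log10 of the unadjusted limma p (vertical axis) for 19938 genes, with 508 genes called higher in red, 720 called lower in blue and the rest in grey. Rad21 lies apart at a log2 change of -3.93, and Nod1 and Trh lie farthest to the right.

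The second question concerned the genes that define pluripotency. Of 18 measured genes of the naive state, 7 were lower, 1 was higher and 10 did not pass, and adjusted over the list alone 9 were lower and 2 higher. Prdm14 fell by 1.82 on the log2 scale (SE 0.12), Klf4, a target of LIF signalling and of the naive network, by 1.23 (SE 0.10, adjusted p = 0.000151), Klf5 by 0.68 (SE 0.08, adjusted p = 0.000742) and Tbx3 by 0.65 (SE 0.09, adjusted p = 0.00189). Nanog was 1.46-fold lower, at 11.16 ± 0.09 against 11.71 ± 0.12 (n = 3, adjusted p = 0.00473 in limma). The 1 higher member, named after its values were seen, was Gbx2, with a log2 change of 0.51, and its call was lost in 3 of the 6 fits without 1 array (adjusted p up to 0.0922, without wt/wt replicate 3). Naive genes as a group ranked lower than other genes (median -0.23, camera adjusted p = 3.55e-05). That call was not reached with an estimated correlation (adjusted p = 0.756), whereas fry, which asks only whether the members move one way, gave an adjusted p of 0.0229.

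Genes of general pluripotency moved both ways. Of 14 measured members 4 were higher and 3 lower, or 5 and 3 when adjusted over the list alone, and the group had no shift (median 0.10, camera adjusted p = 0.593). Lin28a, an RNA-binding protein that blocks maturation of let-7, was 2.50-fold higher (log2 change 1.32, SE 0.11, adjusted p = 0.000157). Sox2 was 1.39-fold lower, at 10.79 ± 0.05 against 11.27 ± 0.02, with an adjusted p of 0.0036 in limma. Fgf4, a target of Oct4 and Sox2, was 1.49-fold lower (adjusted p = 0.00253). Foxd3 had a log2 change of -0.59 (adjusted p = 0.0254) and lost its call without wt/wt replicate 2 or lox/lox replicate 2 or 3 (adjusted p up to 0.0932). Pou5f1, which encodes Oct4, stood at 11.86 ± 0.03 against 12.02 ± 0.04, a log2 change of -0.16 (95% interval -0.33 to -0.001) that did not pass (adjusted p = 0.275). The other higher members, L1td1, Trim71 and Utf1, named after their values were seen, each passed with all 6 arrays and in none of the fits without 1.

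The primed epiblast list holds genes that rise when ES cells leave the naive state. It ranked higher than other genes (12 measured, median 0.22, camera adjusted p = 0.0146; adjusted p = 0.453 with an estimated correlation), and 2 members were higher and 1 lower, or 5 and 2 when adjusted over the list alone. Dnmt3b, a de novo DNA methyltransferase, rose by 0.47 on the log2 scale (SE 0.08, adjusted p = 0.00657). Lef1 had a log2 change of 0.58 (adjusted p = 0.0162) and Zic2 one of -0.57 (adjusted p = 0.0272), and each lost its call in 4 of the 6 fits without 1 array, with an adjusted p of up to 0.0742 for Lef1 without wt/wt replicate 3 and up to 0.127 for Zic2 without lox/lox replicate 2. Otx2 and Fgf5, markers of early primed cells chosen after their values were seen, had log2 changes of 0.18 and 0.15 with adjusted p of 0.454 and 0.463. Targets of Wnt signalling also ranked higher (11 measured, median 0.13, camera adjusted p = 0.0236; adjusted p = 0.932 with an estimated correlation and 0.287 in fry). In that list 2 genes passed, also when adjusted over the list alone, the negative feedback gene Axin2 (log2 change 0.61, SE 0.10, adjusted p = 0.00477) and Lef1, which both lists share. Without lox/lox replicate 1 neither list passed, with adjusted p of 0.0735 for the primed and 0.184 for the Wnt list.

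Fibroblast genes, which would mark feeder cells, had a median log2 change of 0.09 beside these shifts. None of 19 passed in limma, 0 also when adjusted over the list alone, with 3 at an unadjusted p under 0.05, and the list did not pass (camera adjusted p = 0.0848). In wt/wt cells 10 of the 19 lay above the array median, and the cells they came from were not tested. It did pass without wt/wt replicate 1 (adjusted p = 0.0196) or lox/lox replicate 3 (adjusted p = 0.0119). The members with the smallest p were Vim, at 11.80 in lox/lox and 11.56 in wt/wt cells, and Dcn, at 3.67 and 3.45, and the collagen genes Col1a1 and Col3a1, chosen after their values were seen, had log2 changes of -0.03 and 0.14.

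**Figure D3:**
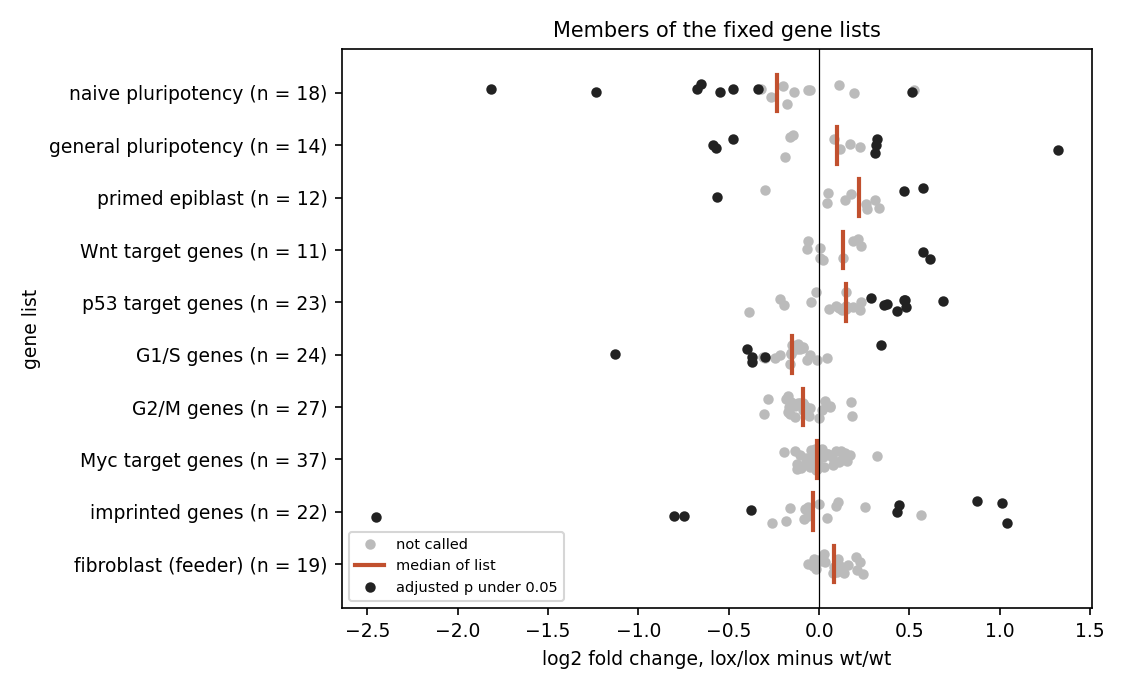
Log2 fold change between lox/lox and wt/wt cells (horizontal axis) of each measured member of 10 gene lists (vertical axis, with the number measured), black where the adjusted limma p was under 0.05 and grey otherwise, with a red line at the median. Naive genes have a median of -0.23, p53 targets one of 0.15 and G1/S genes one of -0.15, while the 37 Myc targets lie around -0.009 and none passed.

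Genes that p53 activates were higher in lox/lox cells as a group. Of 23 measured, 8 rose and none fell at the adjusted threshold, and 10 rose and 1 fell when adjusted over the list alone (median 0.15, camera adjusted p = 2.06e-05; adjusted p = 0.172 with an estimated correlation; fry adjusted p = 0.00465). Plk2, a polo-like kinase, was 1.61-fold higher (SE 0.08 on the log2 scale, adjusted p = 0.000613) and Eda2r, a receptor of the TNF receptor family, 1.39-fold (adjusted p = 0.00405). Sesn2, a stress-induced inhibitor of mTORC1, and Perp, an apoptosis effector, each had a log2 change of 0.47 with adjusted p of 0.0114 and 0.0158. Sesn2 lost its call without wt/wt replicate 3 (adjusted p = 0.0601) and Perp without lox/lox replicate 3 (adjusted p = 0.0514). Plk2 and Eda2r passed in each of the 6 fits without 1 array, and the other 6 called members did not. The number of higher members fell from 8 to 3 without wt/wt replicate 3 or lox/lox replicate 3, the latter with 1 lower member, and to 5 without wt/wt replicate 2 or lox/lox replicate 2. The p53 targets Cdkn1a, Bax and Gdf15 were not analysed here, since no probe set with a single gene symbol was paired with them.

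Genes of the G1/S transition were lower as a group, again by small amounts. Of 24 measured, 5 fell and 1 rose, or 8 and 1 when adjusted over the list alone (median -0.15, camera adjusted p = 2.06e-05; adjusted p = 0.671 with an estimated correlation; fry adjusted p = 0.014). Ccnd3, which encodes cyclin D3, fell by 1.13 on the log2 scale (SE 0.08, adjusted p = 3.95e-05), and was the 1 member that passed in each fit without 1 array. The number of lower members was 2 without wt/wt replicate 2 or 3 or lox/lox replicate 1, and 1 without lox/lox replicate 2. The replication factor genes Mcm4, Cdc45 and Chaf1b had log2 changes of -0.40, -0.37 and -0.37 with adjusted p of 0.0204, 0.0197 and 0.0244. Their calls were lost in 3 or 4 of the 6 fits without 1 array, and without lox/lox replicate 2 their adjusted p were 0.102, 0.0979 and 0.117. Named after their values were seen, Cdc6 was the remaining lower gene (log2 change -0.30, adjusted p up to 0.176 without wt/wt replicate 3) and Ccnd1, cyclin D1, the higher one (log2 change 0.34, adjusted p up to 0.166 without lox/lox replicate 1). Genes of G2 and mitosis had a median of -0.09, and none of 27 passed in limma, 0 also when adjusted over the list alone, with 4 at an unadjusted p under 0.05 (camera adjusted p = 0.136). That list passed without wt/wt replicate 1 (adjusted p = 0.0452) or lox/lox replicate 3 (adjusted p = 0.0211), and without the latter 1 member was lower.

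The title of the study names Myc, so the level of Myc and of its targets was compared. Myc was 2.15-fold higher in lox/lox cells, at 7.64 ± 0.17 against 6.53 ± 0.22 (log2 intensity, mean ± SD, n = 3). The log2 change was 1.11 with a standard error of 0.12 and an adjusted p of 0.000633 in limma, and it lay between 0.99 and 1.20 when each array was left out. Myc lies 47 measured genes from Rad21 on chromosome 15. Of the other 10 measured members of the Myc family and its partners, 1 passed. This was Mycl, at -0.39 (adjusted p = 0.0316), whose call was lost without wt/wt replicate 1 or 3 or lox/lox replicate 2 or 3 (adjusted p up to 0.138). The same pair, Myc and Mycl, passed when adjusted over the list alone, and the family had no shift (camera adjusted p = 0.748). Mycn stood at 9.95 ± 0.04 against 10.10 ± 0.05 and did not pass (adjusted p = 0.309). Myc target genes, mostly of ribosome biogenesis and metabolism, had no member that passed. Of 37, 0 passed in limma over all genes, 0 when adjusted over the list alone and 1 at an unadjusted p under 0.05, and the group had a median of -0.009 and a mean of 0.008 (camera adjusted p = 0.748). The smallest p among the targets was that of Tert, with a log2 change of 0.32 (adjusted p = 0.0814).

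Imprinted genes changed in both directions. Of 22 measured, 5 were higher and 4 lower, or 6 and 5 when adjusted over the list alone, so that the group had no shift (median -0.03, mean -0.02, camera adjusted p = 0.831, direction up). Besides Plagl1, Slc38a4 fell by 0.75 on the log2 scale (SE 0.12, adjusted p = 0.00492), while Cdkn1c, a cyclin-dependent kinase inhibitor, rose by 1.04 (SE 0.12, adjusted p = 0.000751) and Mest by 0.87 (SE 0.10, adjusted p = 0.000755). The remaining called members, named after their values were seen, were Ndn (-0.80), Phlda2 (1.01), Peg3 (-0.38), Usp29 (0.43) and Grb10 (0.45), in log2 changes. Peg3 lost its call in 3 of the fits without 1 array (adjusted p up to 0.0765, without lox/lox replicate 2), and Usp29 and Grb10 in 4 (up to 0.0787 without lox/lox replicate 1 and 0.148 without wt/wt replicate 3). The higher members numbered 3 without wt/wt replicate 2 or 3 or lox/lox replicate 2.

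Lineage markers did not shift as groups in one direction, while single members changed both ways. In fry's test of change in either direction, which 26 of 29 lists passed, the adjusted p were 3.32e-06 for primitive endoderm and 2.72e-05 for trophectoderm genes. Of 19 primitive endoderm genes 2 were higher and 3 lower in limma, the same numbers when adjusted over the list alone (camera adjusted p = 0.831). Lamb1, a laminin chain, rose by 0.78 on the log2 scale (SE 0.08, adjusted p = 0.000378) and Sparc by 0.47 (adjusted p = 0.00386), while the lower members Lamc1, Srgn and Lama1 each lost their call in at least 3 fits without 1 array (adjusted p up to 0.0762, 0.0859 and 0.142). Trophectoderm genes numbered 3 higher and 4 lower of 15, also over the list alone (camera adjusted p = 0.663), among them Fgfr2 at 0.68 (adjusted p = 0.000657), Tead4 at -0.59 (adjusted p = 0.00159) and Tfap2c at -0.87 (adjusted p = 0.00991; 0.0739 over all probe sets). The others, partly named after their values were seen, Krt19 and Ascl2 (higher) and Gata3 and Plet1 (lower), each lost their call in at least 1 fit without 1 array, with adjusted p of up to 0.0569, 0.129, 0.075 and 0.129. Of 13 mesoderm genes 1 was higher and 1 lower, or 2 and 1 over the list alone (camera adjusted p = 0.593), with 2 higher without wt/wt replicate 2 or lox/lox replicate 1. Bmp4 rose by 0.84 (SE 0.10, adjusted p = 0.00104), and Gsc, at -0.66, lost its call without wt/wt replicate 3 or lox/lox replicate 2 (adjusted p up to 0.0661). Of 17 neural genes 2 were lower, Ncam1 and Olig2, at -0.53 and -0.51, and over the list alone 3 were higher and 2 lower (camera adjusted p = 0.302). Both lost their calls without lox/lox replicate 2 (adjusted p = 0.0546 and 0.0744), and Olig2 also without wt/wt replicate 2.

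Signalling and stress genes likewise held single changes without a shift of the list. Of 17 ERK feedback and immediate early genes 3 were higher and 2 lower, or 4 and 2 over the list alone (camera adjusted p = 0.863), with Spry2 at a log2 change of 0.51 (adjusted p = 0.00948; 0.0527 without the 2 arrays apart and 0.0507 over all probe sets) and Ier2 at -0.42 (adjusted p = 0.00709). Dusp4 (0.51), Ier3 (0.61) and Etv4 (-1.02) lost their calls without lox/lox replicate 2, among others, with adjusted p of up to 0.0982, 0.121 and 0.0831. Of 19 genes of the integrated stress response 1 was higher and 2 lower, also over the list alone (camera adjusted p = 0.2, and 0.0133 without wt/wt replicate 3). These were Ddit4 at 0.85, Xbp1 at -0.45 and Chac1 at -0.43, and each lost its call without at least 1 array, with adjusted p of up to 0.112, 0.0507 and 0.0772. Of 15 glycolysis genes Pdk1, a kinase that inhibits pyruvate dehydrogenase, was higher at 1.02 (SE 0.12, adjusted p = 0.00095), and the glucose transporter genes Slc2a3 at -0.56 (adjusted p = 0.00586) and Slc2a1 at -0.61 (adjusted p = 0.00829; 0.0503 without lox/lox replicate 2) were lower, the same numbers over the list alone (camera adjusted p = 0.663). Of 20 interferon response genes 1 passed, Ddx58, the cytosolic RNA sensor, at 0.78 (adjusted p = 0.000572), also over the list alone, and 2 were higher without lox/lox replicate 1 (camera adjusted p = 0.605 for the list). Of 17 sterol synthesis genes Dhcr7 was higher at 0.36 and Stard4 lower at -0.34, with adjusted p of up to 0.134 and 0.187 in fits without 1 array, and over the list alone 1 was higher and 2 lower (camera adjusted p = 0.426).

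Of 12 housekeeping genes 3 were lower and none higher, or 4 lower over the list alone (camera adjusted p = 0.2). These were B2m at -0.92 (adjusted p = 0.00088), Tfrc at -0.66 (adjusted p = 0.000657) and Gusb at -0.35 (adjusted p = 0.0246; up to 0.111 without wt/wt replicate 3). Germline genes had 1 higher and 2 lower of 18, or 4 and 2 over the list alone (camera adjusted p = 0.281), namely Hormad1 at 0.60, Piwil2 at -0.43 and Dazl at -0.66, the last with an adjusted p of up to 0.115 without lox/lox replicate 2. Without lox/lox replicate 1 there were 3 higher germline genes, and Hormad1 lost its call without the 2 arrays apart (adjusted p = 0.055) or over all probe sets (adjusted p = 0.0633). In the list of genes of 2-cell-like cells, 6 of 18 members were measured, and Tdpoz3 at 0.78, Zfp352 at 0.32 and Pramel7 at -0.94 passed, also over the list alone, Zfp352 in no fit without 1 array and Pramel7 not without the 2 arrays apart (adjusted p = 0.0736; camera adjusted p = 0.591 for the list). In wt/wt cells 1 of these 6 lay above the array median, while Tdpoz3, Zfp352 and Pramel7 lay below it, at 4.2, 4.3 and 4.8. Gene clusters known for long-range regulation had few or no calls. Hoxc4, at -0.47, was the 1 called gene of 37 Hox genes, also over the list alone (adjusted p up to 0.113 without lox/lox replicate 2; camera adjusted p = 0.831), and none of 22 clustered protocadherin genes passed in limma, 0 also over the list alone, with 2 at an unadjusted p under 0.05 (camera adjusted p = 0.863). All 22 protocadherin genes were Pcdhb genes, and the list held no Pcdha or Pcdhg gene, so those clusters were not tested as a list. None of these 22 lay above the array median in wt/wt cells, so that a fall could hardly have been seen. Hoxc4 also lay below that median, at 4.8 in wt/wt and 4.4 in lox/lox cells. Of 58 ribosomal protein genes Rps3a1 passed (-0.38; 0 genes over the list alone, camera adjusted p = 0.426 for the list), and of 31 replication-dependent histone genes H2ac1 (0.38; 1 gene over the list alone, camera adjusted p = 0.919 for the list), each losing its call in at least 4 fits without 1 array (adjusted p up to 0.143 and 0.111), and without wt/wt replicate 1 there was 1 lower histone gene.

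Because the lines can differ in chromosome content, each chromosome was tested as a list. Of 20 chromosomes none was shifted (camera, smallest adjusted p = 0.881), 0 had an unadjusted p under 0.05 with a preset or an estimated correlation, and their medians ran from -0.02 to 0.007. Rad21 lies on chromosome 15, and in a mixed background the genotypes can carry different strain sequence around it. Of the 100 measured genes nearest to Rad21 in gene order, 4 were higher and 2 lower, a share of 6% against 6.17% of the 19744 other genes placed on chromosomes (Fisher's exact test, two-sided p = 1, odds ratio 0.971). The 6 called genes, named after their values were seen, include Myc (log2 change 1.11), which lies 47 measured genes from Rad21, and Pvt1 (0.57), which lies beside Myc at 48. Aard, the measured gene next to Rad21 on one side, had a log2 change of -1.14 (SE 0.12, adjusted p = 0.000426 in limma), while Utp23, that on the other side, had -0.05 and did not pass (adjusted p = 0.854). Of the other called neighbours, Dcstamp had -0.96, Zhx1 0.48 and Grhl2 0.40. An effect of strain sequence linked to Rad21 on single genes of this window was not tested.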

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

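Leaving out both arrays that stood apart, or giving them a covariate, was chosen after seeing the data. No gene of the 1228 changed sign under the gene-level settings tried. In all 1228 the arrays did not overlap between genotypes, so leaving out or weighting arrays could not change a sign. Quantile normalization, median centring and cyclic loess called 1359, 1186 and 1350 genes, of which 1193, 1126 and 1190 were shared. The count was 1424 without dim genes, 1523 with trend and robust, 1717 with array weights and 1635 with the covariate, of which 1145, 1181, 1219 and 1228 were shared. It fell to 808 (319 higher) over all probe sets, for which the cause was not tested. That setting fitted and adjusted over 35556 probe sets in place of 1 per gene, so 808 is not comparable with the counts of genes. By construction the count of genes fell to 451 (184 higher, 267 lower) at 1.5-fold and 553 (233 and 320) at an adjusted p under 0.01. It was 697 (267 and 430) without the 2 arrays apart, of which 638 were shared. Of 86 named genes that passed, 30 lost their call without the 2 arrays apart, 32 over all probe sets, 5 with the replicate block, 3 with median centring, and 1 each with cyclic loess and with trend and robust. Without single arrays it ran from 626 to 1132, with 269 to 484 higher and 340 to 686 lower, as fewer arrays give less power. Rad21 (log2 change -3.95 to -3.91) and Myc (0.99 to 1.20) passed in each of these fits.

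With an estimated correlation in camera 0 lists were called in place of 5. The adjusted p were 0.7557 for naive genes, 0.1719 for p53 targets, 0.6707 for G1/S genes, 0.4531 for primed and 0.9317 for Wnt genes. That form of the test also rests on the 4 residual degrees of freedom. The lost calls therefore do not show by themselves that members correlate. In fry, Wnt targets had 0.2867. Without single arrays 3 to 7 lists were called, with an adjusted p of 0.0119 to 0.0735 for primed and 0.00374 to 0.184 for Wnt genes, both lost without lox/lox replicate 1, and the cause was not tested. The 5 lists were called with the same direction under the other settings. Of the lists not called, ribosomal proteins and G2/M genes passed over all probe sets (both 0.0355) and fibroblast genes with array weights (0.0243). Over all probe sets, each probe set of a gene counted as a member, such as the 14 of Rps12. The passes in that setting thus count repeated measurements of a gene as separate members. With the replicate number as a block 1086 genes were called, of which 1006 were shared, and no list changed its call. Deviations of samples with the same number correlated at 0.101, -0.228 and -0.103, below those of wt/wt replicate 2 with lox/lox replicate 3 (0.322), so not every sample correlates best with its own number, and the numbers were not taken as pairs. Signal over background limits what can be said of genes near or below the array median. Among called list members, Olig2, Srgn, Usp29, Zfp352, Pramel7 and Hoxc4 lay below it in both genotypes.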

Other observations

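All genes named in this paragraph were chosen after their values were seen. Cd3d and Cd3e, which lie beside Cd3g on chromosome 9, had log2 changes of -1.70 (SE 0.17, adjusted p = 0.000384 in limma) and -0.75 (SE 0.11, adjusted p = 0.00363), next to -2.39 for Cd3g. Lefty2, a close relative of Lefty1, had 0.83 (SE 0.17, adjusted p = 0.0185), next to 1.80 for Lefty1.

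The tests of an X chromosome loss, of dilution, of scaling and of cycling cells were chosen after the result was seen. The real grouping called 1228 genes and the highest of the 9 other splits of the 6 arrays called 0, so that 1 of 10 splits gave as many, which is too few splits for a share under 0.05.

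Naive pluripotency genes ranked lower in lox/lox cells, with 7 of 18 lower, 1 higher and 10 that did not pass (camera adjusted p = 3.55e-05; adjusted p = 0.756 with an estimated correlation). Female ES cells can lose an X chromosome, but the 370 X-linked genes above the array median had a median log2 change of -0.029 (bootstrap 95% interval -0.047 to -0.010). This is far from the size of 0.3 that was set as the least to count as such a loss. A loss in a small part of the cells would give a smaller change and is not covered by this test. Other cells that lack both naive and general pluripotency genes, mixed into the lox/lox cultures, cannot be told apart, because the medians of general and naive genes differed by 0.33 with an interval that holds 0 (-0.06 to 0.63). Loss of Rad21 and a difference between the lines from before treatment both stay open and were not tested, as no untreated samples entered the comparison.

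Higher p53 targets and lower G1/S genes were found together, though neither list passed with an estimated correlation (adjusted p = 0.172 and 0.671). Both lists kept their call and direction under quantile and cyclic loess scaling, in 4 of 4 tests. The values were already RMA output, and camera ranks members against other genes, so these tests could hardly have failed. Whether scaling of the arrays plays a part is therefore not decided. A lower share of cycling cells cannot be told apart from a change within G1/S genes, because the medians of G2/M and G1/S genes differed by 0.062 with an interval that holds 0 (-0.011 to 0.164).

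The number of imprinted genes called, 9 of 22, was above that of 10000 random lists matched on mean expression, which had a median of 1, a central 95% of 0 to 4 and a highest count of 7 (permutation test, one-sided p = 1e-04, the smallest that these lists can give). Chance given their expression level is argued against, for genes that change independently. The random lists were matched on mean expression alone and do not cover members that change together. The same test of all 29 lists, chosen after the result was seen, passed in 7, so that such an excess was not confined to imprinted genes: 7 of 15 trophectoderm genes were called (adjusted p = 0.00193, as for imprinted genes). Imprinted genes are known to drift between ES cell lines, so a difference between the lines that was there before 4-OHT may account for the pattern as well as loss of cohesin, and without untreated samples in the comparison neither was tested.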
